A study of Carica papaya with 55 samples.

How the data were processed

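The material was RNA from buds, dissected floral organs and gametophytes of papaya 'AU9' female and male flowers, 55 libraries in 19 groups. Per the file headers, the values are counts of fragments over exons summed by gene name, made with featureCounts 2.0.0 in paired mode, with reads that map to several places counted at each of them and no strand setting in any of the 55 headers. The processing notes of the submitters name FastQC 0.11.5, Trimmomatic 0.36, HISAT2 2.0.5, SAMtools 1.3.1 and featureCounts 1.5.2, a version that differs from the headers. The tables cover features of the X and Y sex-linked regions only, so totals per library (21475 to 106846 counts) are not sequencing depth and scaling rests on sex-linked features alone. The genome build is not given in the sources used here. The headers place the 6 bud libraries in one folder and the other 49 in another, so no test set buds against organs. Levels of buds shown beside those of organs may also differ by folder.

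Names of features are those of the files. None matched an identifier or symbol in the reference table of 48816 genes, so the lists by function that had been fixed had 0 matched members, and the lists used were X-located and Y-located features. Results planned for CpMDAR4 and for its allele shares were not run. No set test was run, because the tables hold fewer features than the plan required.

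Counts were scaled by the trimmed mean of M-values (TMM), filtered by group with filterByExpr (54 features left out, 139 tested) and fitted with edgeR 4.0.16 in R 4.3.3, in 1 quasi-likelihood model with a coefficient for each of the 19 groups and robust estimation, prior count 0.125. Contrasts gave male against female buds, pistillode, stamen and pistil against each other as means over S1 to S5, ovule against pistil and pollen against stamen at S5, late (S4 and S5) against early (S1 to S3) in each organ, and differences of these changes between organs. P-values were two-sided, adjusted by Benjamini-Hochberg over the features tested, with a threshold of 0.05, and again over the X-located or Y-located list alone. Groups, contrasts, lists, the naming rule and most alternatives were fixed before the data were examined.

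The naming rule took up to 10 features with the largest change in each direction per comparison, among those with an adjusted p under 0.05, a mean of at least 10 counts per library in the higher group and no overlap between the libraries of the groups in at least 1 stage. Levels of CpXY36_X in pistils and pollen, of CpXY41_MSY and CpXY34_MSY in pistils and of CpXY21_X by stage in stamens, the Y share without CpY17_MSY, the ratio per exon base and the pairs named for Y shares, were chosen after their values were seen. Where a group had 0 counts, a fold was computed against 3 counts over the group and is a lower bound. Other ratios with few counts carry a 95% exact binomial counting interval.

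Pairs of X and Y copies were classed by the Y copy's share of the pair's female counts, for pairs with at least 100 such counts: separate under 5%, shared over 25%, partly shared between. The ratio of Y to X counts within male libraries was added after the data were seen. It was computed for separate pairs with at least 20 counts per pair in every library and a mean of at least 10 counts for each copy in a group. The mean over males also left out pairs in which a copy had no counts in some library. It is a ratio of counts without exon length, which is the same in every library and leaves contrasts between groups unchanged, and the mean over males was also taken per exon base. It was taken on the log2 scale with a pseudocount of 0.5 and tested with limma 3.58.1, with Benjamini-Hochberg adjustment over pairs. The stamen and pistillode ratios were also tested by permutation within stages with 1e+05 resamples.

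Alternatives were size factors by the median of ratios, table totals, TMM on X features, the DESeq2 1.42.0 Wald test, other count filters, fits on the groups compared alone or without pollen, replicate number as a block, and each library left out in turn. Added after the data were seen were tests on features without shared copies and without libraries that stood apart. The former left out both shared and partly shared pairs and kept pairs with too few female counts to class. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

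The fit was tested on simulated data drawn from the observed means and dispersions, in 10 runs for each of the 11 comparisons with 40 changed features. The groups compared started from a common mean, and equal numbers of features were raised and lowered. Observed contrasts of the sexes were one-sided on the Y, with 45 Y-located features higher and 6 lower in male buds. The shares that follow were not measured for such one-sided data. Changes of 4-fold were found in 95.5 to 100% of cases and changes of 2-fold in 77 to 98%. The share of false calls was 2.12 to 20.2% with TMM and 1.53 to 5.46% with the scaling known, so that with so few features scaling adds false changes. Their median size on the log2 scale ran from 0.31 for stamen against pistillode to 0.60 for ovule against pistil, with 0.54 for buds and 0.58 for pollen against stamen. For the ratio, 2-fold moves were found in 97.5% of moved pairs for stamen against pistillode (6 of 122 calls false), 77.5% for pollen against stamen (6 of 99), 99.1% for late against early stamen (3 of 117), 88.3% for late against early pistillode (5 of 111) and 100% for the mean of males (1 of 121). Replicates differed by more than counting error: over 53 pairs of libraries within groups, chi-square per degree of freedom ran from 1.46 to 209, with a median of 10.2.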

Results

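RNA from papaya (Carica papaya) 'AU9' flowers was sequenced to follow the expression of sex-linked genes in female and male reproductive organs. The deposited tables held fragment counts for features of the sex-linked regions alone, 97 on the X chromosome and 96 on the male-specific region of the Y (named with the suffix MSY). They covered 55 libraries in 19 groups, 21 female and 34 male. Floral stage was given by bud length: under 1 mm for S0, 1 to 1.5 mm for S1, 2 to 4.5 mm for S2, 4.5 to 6.5 mm for S3 (before meiosis), 7 to 12 mm for S4 (after meiosis) and 15 to 20 mm for S5 (mature flower). Whole buds were sampled at S0, and pistils of females, and pistillodes (the aborted pistils of male flowers) and stamens of males, from S1 to S5. Ovules and pollen were sampled at S5. Every group had 3 libraries except the pistillodes at S2 and at S3, with 2 each. The series concerns CpMDAR4 alleles; no feature of the tables is named so, and CpMDAR4 was not analysed here.

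The total per library ran from 21475 to 106846 counts with a median of 64618. These are totals over sex-linked features alone, not the depth of the libraries. Female totals ran from 48132 to 92119 counts, and pollen totals from 27741 to 28555. Levels are given as CPM relative to the scaled total of sex-linked counts, as mean ± SD. A count of 0 allows up to 3 counts, and such floors, like the counting intervals on ratios, cover counting error only. The sample labels do not say whether replicates came from separate plants, so the p-values measure the spread between these samples. The genome build behind the coordinates is not given in the sources used here.

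Y-labelled features took a mean of 26.8 ± 0.616% of the counts in female libraries (SD, n = 21, range 25.5 to 28.2%) and 49.4 to 68.6% in male libraries (n = 34). Among males the share was 52.0 ± 0.116% in buds (n = 3), 49.9 ± 0.469% in S3 stamens (n = 3) and 67.3 ± 1.56% in pollen (n = 3). Mature pistillodes held 58.1 ± 7.75% (n = 3), with a range of 53.5 to 67.0%, and in the library at 67.0% PCpY4_MSY alone took 28.2% of the counts. The high share of pollen came from 1 feature: CpY17_MSY took 32.7 ± 2.66% of pollen counts and 7.86 ± 5.23% of S5 stamen counts, and without it the Y share was 51.4 ± 0.522% in pollen and 49.9 ± 0.421% in S5 stamens. CpY19_MSY, which has no X partner (Y, 4002488 to 4004000), separated the sexes in every library, with 0 to 1 counts in each female and 148 to 880 in each male. Of the 27 Y features without an X partner, 18 had no counts in any female library and 4 had counts in all 21, namely CpY17_MSY, PXYCpXY3_MSY, PCpY4_MSY and PCpY10_MSY. Together the 27 took 1.01% of female counts.

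**Figure D1:**
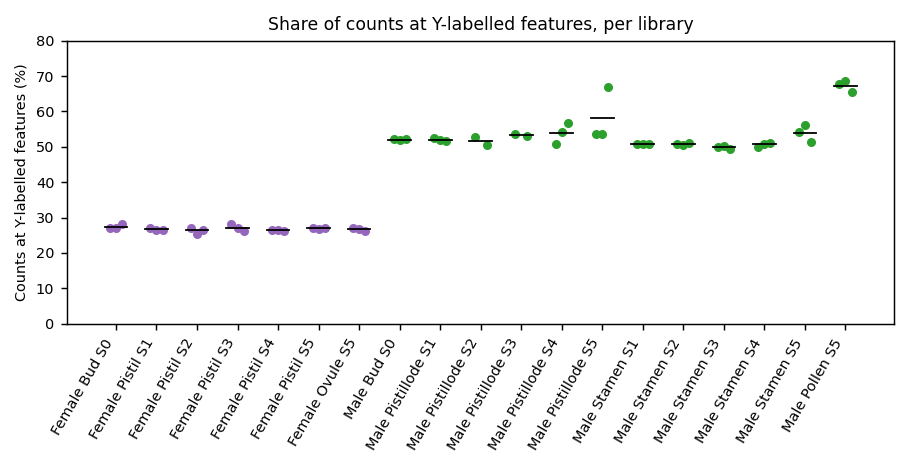
Share of counts at Y-labelled features (vertical axis, percent) in each of the 55 libraries, by group along the horizontal axis; points are libraries and short bars are group means. All 21 female libraries lie between 25.5 and 28.2%, below every male library (49.4 to 68.6%).

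For 69 genes the tables listed a copy on each chromosome. Females carry no Y, so their counts at a Y copy come from other sequences, among which the X copy was not told apart from the rest. Pairs were classed by these counts. Among pairs with at least 100 female counts, the Y copy took under 5% of the pair's female counts in 21 pairs, here called separate, and over 25% in 26 pairs, here called shared. Another 10 pairs lay between these limits and 12 had too few female counts. The latter, among them CpXY4, CpXY10 and CpXY18, were not classed, and the chromosome of origin of their counts is uncertain. CpXY11 (0.0574%), CpXY8 (0.132%) and CpXY7 (0.562%) were separate, and CpXY36 (49.4%), CpXY38 (49.9%) and CpXY41 (67.0%) were shared. Values at a copy of a shared or partly shared pair are counts at the named feature, and they are uncertain as to the chromosome of origin. A read that maps to both copies is counted at each, so numbers of features are not numbers of distinct genes. The copies of such pairs did not always take equal counts: S5 pistils held 8011 CPM at CpXY34_X and 2819 CPM at CpXY34_MSY.

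**Figure D2:**
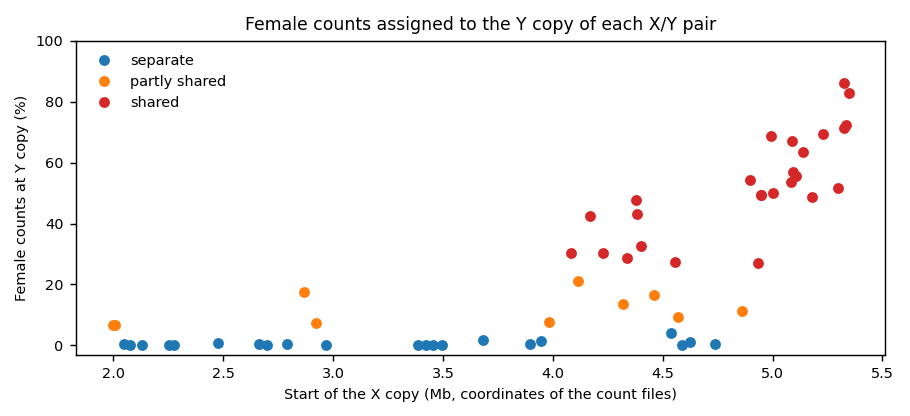
Share of each pair's female counts assigned to the Y copy (vertical axis, percent) against the start of the X copy (horizontal axis, Mb), 1 point per pair with at least 100 female counts. None of the 21 pairs before CpXY15 lies above 25%, and 13 of the 18 pairs from CpXY33 on lie above 50%.

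The comparison of male with female buds under 1 mm asked how sex-linked expression differed before organs could be dissected. Among Y copies of separate pairs, CpXY8_MSY stood at 21771 ± 1108 CPM in male and 82 ± 98 CPM in female buds (n = 3 each), and CpXY11_MSY at 15331 ± 1143 against 41 ± 56 CPM. Not every such copy had counts: PYCpXY7 had 0 counts at its Y copy in male buds and a mean of 696 at its X copy. PCpY1_MSY (Y, 477941 to 478677) reached 7524 ± 1006 CPM in male buds, against 25 ± 31 CPM in female buds. PYCpXY5_MSY, CpY20_MSY and PXYCpXY1_MSY had no counts in female buds and were at least 64.7-fold, 55.5-fold and 27.3-fold higher in male buds, with 3 counts over the group as the floor. CpY19_MSY, with 2 counts over the female buds, was higher by a ratio of 944 (95% counting interval 261 to 7797). The X copies of CpXY8 and CpXY11 moved the other way: CpXY8_X was at 23030 ± 1775 CPM in male and 52441 ± 4736 CPM in female buds, and CpXY11_X at 16914 ± 582 against 43496 ± 2271 CPM.

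With the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment, 90 of 139 tested features differed between the buds, 52 higher and 38 lower in males. Of 67 X-located features 7 rose, 32 fell and 28 did not pass, and 39 passed when adjusted over the list alone. Of 72 Y-located features, 45 rose, 6 fell and 21 did not pass, and 51 passed when adjusted over the list alone. The log2 difference was -1.19 (SE 0.14, adjusted p = 3.2e-10) for CpXY8_X, -1.36 (SE 0.19, adjusted p = 6.1e-08) for CpXY11_X and -1.13 (SE 0.12, adjusted p = 9.5e-11) for CpXY9_X, all of separate pairs, and -1.63 (SE 0.26, adjusted p = 6.1e-07) for CpXY37_X of a shared pair. X copies of separate pairs fell in 17 of 21 cases and rose in 0, with a median log2 difference of -0.91, and those of shared pairs rose in 6 and fell in 8 of 27, with a median of 0.03. Scaling set the level from which these are read: scaled on X features alone, 70 features rose and 13 fell, and the median over all features moved from 0.08 to 0.65. On that scaling X copies of separate pairs fell in 9 of 21 cases and rose in 0, and those of shared pairs rose in 13 and fell in 2 of 27. The medians were -0.33 for separate, 0.01 for partly shared and 0.60 for shared pairs, so that the sign for partly shared pairs (-0.56 before) turned, and CpX1 (-1.22, SE 0.32) no longer passed, at -0.65 (adjusted p = 0.0844).

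Pistillodes were compared with pistils of the same stage to set the aborted organ of males beside the functional organ of females. CpXY15_X of a partly shared pair (X, 3980708 to 4007398), was lower in pistillodes at each stage, at 6034 ± 634 against 16844 ± 2997 CPM at S1 and 4321 ± 451 against 18392 ± 5203 CPM at S5 (n = 3 each). CpXY34_X of a shared pair fell from 3216 ± 195 CPM in S1 pistillodes to 1772 ± 182 CPM at S5, while pistils held 6339 ± 558 and 8011 ± 345 CPM. CpXY31_X was detected in pistils, at 715 ± 207 CPM at S1 and 87 ± 32 CPM at S5, and had 3 counts over the 13 pistillode libraries against 285 over the 15 pistil libraries, a ratio of 0.0152 (95% counting interval 0.00311 to 0.0448). CpXY7_MSY, the Y copy of a separate pair, rose from 14209 ± 1924 CPM in S1 pistillodes to 47397 ± 7766 CPM at S5 and stayed between 53 ± 17 and 130 ± 36 CPM in pistils. CpXY41_MSY of a shared pair was at 74976 ± 10031 CPM in S5 pistillodes and 11647 ± 926 CPM in S5 pistils.

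By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 115 of 139 features differed over S1 to S5, 64 higher and 51 lower in pistillodes. Among 67 X-located features 14 rose, 42 fell and 11 did not pass, with 56 when adjusted over the list alone. Of 72 Y-located features, 50 rose, 9 fell and 13 did not pass, with 59 when adjusted over the list alone. The mean log2 difference was -1.73 (SE 0.15, adjusted p = 7.5e-14) for CpXY15_X, -1.40 (SE 0.07, adjusted p = 9.7e-23) for CpXY34_X, -1.42 (SE 0.09, adjusted p = 7.6e-18) for CpXY11_X and 8.12 (SE 0.21, adjusted p = 9.0e-33) for CpXY7_MSY. PCpY9_MSY and CpY20_MSY had no counts in 15 pistil libraries and were at least 346-fold and 328-fold higher in pistillodes. X copies of separate pairs fell in 18 of 21 cases and rose in 0 (median -1.01), those of partly shared pairs fell in all 10 (median -1.04, and in 6 when scaled on X features), and those of shared pairs rose in 12 and fell in 13 of 27 (median 0.01). Scaled on X features, 82 features rose and 30 fell, the median of all features moved from 0.19 to 0.79, and X copies of separate pairs rose in 1 and fell in 17 cases (median -0.41) while those of shared pairs rose in 17 and fell in 5 (median 0.60). With table totals the median for shared pairs was -0.09.

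Stamens and pistillodes are both organs of male flowers, so sex-chromosome content does not differ between them. CpXY36_X of a shared pair (X, 4948529 to 4951174) rose in stamens from 25326 ± 1239 CPM at S1 to 156552 ± 16987 at S4 and 272578 ± 36687 CPM at S5 (n = 3 each), and stood between 35543 ± 2540 and 40121 ± 6195 CPM in pistillodes. CpY1_MSY rose from 403 ± 293 CPM in S1 stamens to 15019 ± 2756 CPM at S5, against 1032 ± 565 CPM in S5 pistillodes. CpXY18_X, of a pair with too few female counts to class, was between 0 and 44 ± 76 CPM in pistillodes and reached 3042 ± 2009 CPM in S5 stamens. In the other direction, CpXY26_MSY of a partly shared pair was at 9978 ± 1043 CPM in S5 pistillodes and 1091 ± 369 CPM in S5 stamens, and CpXY7_MSY was at 47397 ± 7766 and 11686 ± 1303 CPM.

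Across S1 to S5, 71 of 139 features differed between stamen and pistillode by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 23 higher and 48 lower in stamens. X-located features numbered 67, of which 14 rose, 22 fell and 31 did not pass (36 when adjusted over the list alone). Of 72 Y-located features, 9 rose, 26 fell and 37 did not pass (35 when adjusted over the list alone). Log2 differences were 5.42 (SE 0.54, adjusted p = 2.3e-11) for CpXY18_X, 3.50 (SE 0.34, adjusted p = 1.5e-11) for CpY1_MSY, 2.07 (SE 0.16, adjusted p = 1.7e-14) for CpXY21_X of a partly shared pair, 1.03 (SE 0.07, adjusted p = 1.3e-16) for CpXY36_X of a shared pair, -1.42 (SE 0.09, adjusted p = 1.3e-16) for CpXY26_MSY of a partly shared pair and -1.09 (SE 0.14, adjusted p = 1.2e-08) for CpXY7_MSY. Counted stage by stage, 14 features passed at S1, 13 at S2, 40 at S3, 61 at S4 and 79 at S5. For CpXY36_X the stage values ran from -0.49 (SE 0.14, adjusted p = 0.014) at S1 to 2.87 (SE 0.15, adjusted p = 7.7e-20) at S5, and for CpXY15_X from 0.50 (SE 0.31, adjusted p = 0.42) to -2.90 (SE 0.35, adjusted p = 2.2e-09). PCpY4_MSY fell by 4.04 (SE 0.69) and did not pass with stage and replicate number as a block (-2.11, adjusted p = 0.0999). Scaling moved the split, to 32 up and 39 down on X features and to 16 up and 57 down with table totals, where the median of all features moved from -0.14 to -0.25. Among features without shared copies 13 were up and 11 down.

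**Figure D3:**
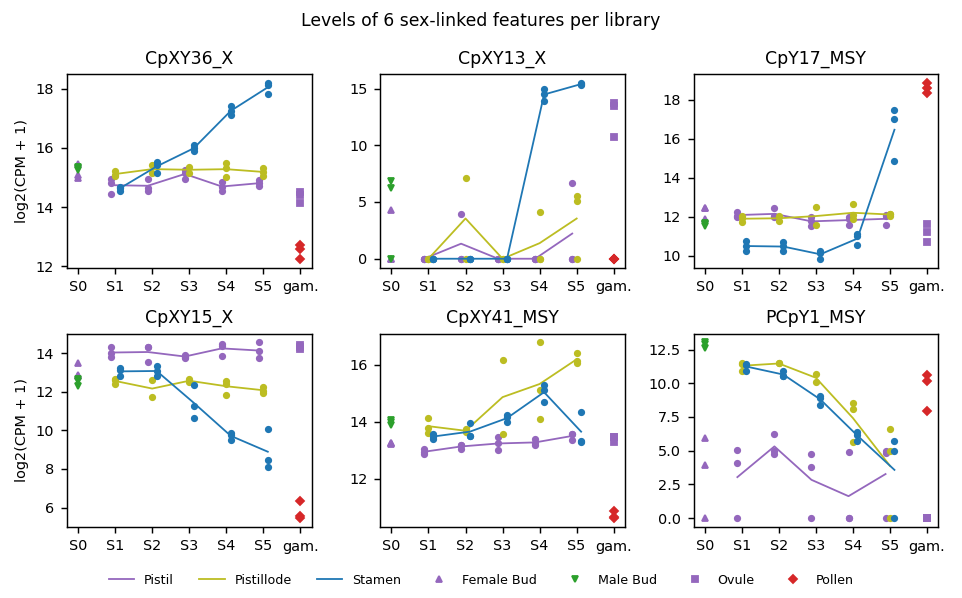
Levels of 6 features (log2 of CPM plus 1, vertical axes) across buds (S0), organs (S1 to S5) and gametophytes; points are libraries and lines join the means of the log2 values of pistils, pistillodes and stamens. CpXY36_X climbs in stamens to 272578 CPM at S5, CpXY13_X appears in S4 and S5 stamens and CpY17_MSY reaches 402172 CPM in pollen. CpXY15_X falls in stamens, CpXY41_MSY reaches 74976 CPM in S5 pistillodes, and PCpY1_MSY is lower at S5 than at S1 in stamens and pistillodes.

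Stamens were also compared with pistils, the functional male and female organs. CpXY15_X of a partly shared pair was at 572 ± 446 CPM in S5 stamens and 18392 ± 5203 CPM in S5 pistils (n = 3 each). CpXY34_X of a shared pair stood at 415 ± 47 against 8011 ± 345 CPM, and CpXY8_X of a separate pair at 12192 ± 4010 against 51305 ± 1833 CPM. CpXY8_MSY was at 10661 ± 3350 CPM in S5 stamens and 68 ± 45 CPM in S5 pistils. CpXY36_X was at 272578 ± 36687 CPM in S5 stamens and 28694 ± 1974 CPM in S5 pistils. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 116 of 139 features differed over S1 to S5, 64 higher and 52 lower in stamens. In the X-located list of 67, 16 rose, 42 fell and 9 did not pass (58 when adjusted over the list alone), and of 72 Y-located features 48 rose, 10 fell and 14 did not pass (58 when adjusted over the list alone). Log2 differences were -2.75 (SE 0.15, adjusted p = 8.8e-21) for CpXY15_X, -2.10 (SE 0.06, adjusted p = 6.8e-30) for CpXY34_X, -1.69 (SE 0.06, adjusted p = 5.0e-27) for CpXY8_X and 7.80 (SE 0.19, adjusted p = 3.1e-33) for CpXY8_MSY. PCpY9_MSY, CpY20_MSY and PXYCpXY1_MSY, at 0 counts in pistils, were at least 273-fold, 266-fold and 159-fold higher in stamens. X copies of separate pairs fell in 20 of 21 cases (median -1.18), and in 12 with 2 higher when scaled on X features (median -0.49), a scaling that turned the median of shared pairs from -0.16 to 0.52. Scaled on X features, 82 features rose and 26 fell, and the median of all features moved from 0.45 to 1.13 (0.27 with table totals).

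Ovules were compared with pistils, both of mature female flowers (S5). CpXY13_X (X, 3895165 to 3898270) was at 8860 ± 6334 CPM in ovules and 33 ± 58 CPM in pistils (n = 3 each), with 130 to 1031 counts in the ovule libraries and 6 over the 3 pistil libraries. CpXY17_X of a partly shared pair was lower in ovules, at 3932 ± 714 against 8743 ± 1373 CPM. CpXY38_X of a shared pair was higher, at 8064 ± 1000 against 5212 ± 136 CPM. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment passed 12 of 139 features, 7 higher and 5 lower in ovules. Of 67 X-located features 4 rose, 4 fell and 59 did not pass (8 when adjusted over the list alone), and of 72 Y-located features 3 rose, 1 fell and 68 did not pass (3 when adjusted over the list alone). The log2 difference was 8.28 (SE 0.89, adjusted p = 3.3e-07) for CpXY13_X, -1.15 (SE 0.18, adjusted p = 6.7e-06) for CpXY17_X and 0.63 (SE 0.14, adjusted p = 0.0015) for CpXY38_X. With the DESeq2 Wald test CpXY13_X had a similar log2 difference of 7.95 and did not pass (adjusted p = 0.071). False calls in simulated data of this comparison had a median size of 0.60, near that of CpXY38_X. Without pistil replicate 2 at S5, and without ovule replicate 3, 5 features passed, and the direction of the split turned when scaled by the median of ratios (4 up and 8 down) and with DESeq2 (3 up and 7 down).

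Pollen was compared with stamens, both of mature male flowers (S5). CpY17_MSY (Y, 3981090 to 3985922) reached 402172 ± 67665 CPM in pollen and 115745 ± 78570 CPM in S5 stamens (n = 3 each), after 1090 ± 148 to 1919 ± 373 CPM in S1 to S4 stamens. Female groups, which have no Y, also had counts at this feature, at 2424 ± 759 to 5014 ± 1055 CPM. CpXY11_X rose from 6084 ± 2360 to 33960 ± 5286 CPM and CpXY43_X of a shared pair from 7408 to 24736 CPM. In the other direction CpXY13_X had 0 counts in pollen against 8892 in stamens, at least 998-fold lower, and CpXY38_X of a shared pair had 1 count against 2271, a ratio of 0.00131 (95% counting interval 3.3e-05 to 0.0073). CpXY36_X of a shared pair fell from 272578 ± 36687 to 5896 ± 914 CPM.

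In pollen, 100 of 139 features differed from S5 stamens by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 35 higher and 65 lower. Among 67 X-located features 19 rose, 31 fell and 17 did not pass (50 when adjusted over the list alone), and of 72 Y-located features 16 rose, 34 fell and 22 did not pass (50 when adjusted over the list alone). Log2 differences were 1.80 (SE 0.31, adjusted p = 1.8e-06) for CpY17_MSY, 2.48 (SE 0.20, adjusted p = 2.3e-14) for CpXY11_X and 1.74 (SE 0.20, adjusted p = 3.0e-10) for CpXY43_X. PCpY1_MSY had 67 counts in pollen and 6 in stamens, a ratio of 33.2 (95% counting interval 14.5 to 93.6, adjusted p = 8.9e-08). CpX15 and CpXY33_MSY had no counts in pollen and were at least 23.0-fold and 12.8-fold lower. The median of all features was -0.57, and -0.18 when scaled by the median of ratios and -0.32 with table totals. The rise of CpXY40_X did not pass without stamen replicate 3 (log2 difference 1.63, adjusted p = 0.052).

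Change with bud age was tested in each organ as S4 and S5 (after meiosis) against S1 to S3. In pistils CpXY25_X of a shared pair rose from 754 ± 315 CPM at S1 to 3638 ± 2962 CPM at S5 (n = 3 each), CpXY37_X of a shared pair fell from 10056 ± 584 to 5401 ± 1367 CPM, and CpXY31_X fell from 715 ± 207 to 87 ± 32 CPM. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment passed 23 of 139 features, 7 higher and 16 lower late. X-located features numbered 67, of which 2 rose, 9 fell and 56 did not pass (11 when adjusted over the list alone). Of 72 Y-located features, 5 rose, 7 fell and 60 did not pass (12 when adjusted over the list alone). Females carry no Y, so these Y-located calls are not Y expression. A gene could be called at both copies, as CpXY35 was. Log2 changes were 1.64 (SE 0.22, adjusted p = 9.7e-07) for CpXY25_X, -0.72 (SE 0.17, adjusted p = 0.0017) for CpXY37_X and -2.03 (SE 0.49, adjusted p = 0.0033) for CpXY31_X. Among features without shared copies none passed (0 by edgeR, with 13 at an unadjusted p under 0.05), and CpXY31_X stood at -1.92 (adjusted p = 0.0538). The split depended on scaling, at 11 up and 13 down by the median of ratios, 12 and 14 with table totals, and 14 and 13 on X features, and without a count filter it was 14 up and 10 down.

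In pistillodes, CpXY41_MSY rose from 14893 ± 2867 CPM at S1 to 74976 ± 10031 CPM at S5 and CpXY19_MSY from 2188 ± 289 to 7800 ± 2532 CPM (n = 3 each), both of shared pairs. CpXY7_MSY rose from 14209 ± 1924 to 47397 ± 7766 CPM. PCpY1_MSY fell from 2565 ± 553 CPM at S1 to 43 ± 51 CPM at S5 and CpXY17_X of a partly shared pair from 8311 ± 748 to 2336 ± 183 CPM. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment 33 of 139 features changed, 19 up and 14 down. In the X-located list of 67, 11 rose, 8 fell and 48 did not pass (19 when adjusted over the list alone), and of 72 Y-located features 8 rose, 6 fell and 58 did not pass (14 when adjusted over the list alone). Log2 changes were 1.66 (SE 0.26, adjusted p = 2.5e-06) for CpXY41_MSY, 1.41 (SE 0.24, adjusted p = 1.2e-05) for CpXY19_MSY, 1.01 (SE 0.21, adjusted p = 0.00019) for CpXY7_MSY, -4.67 (SE 0.46, adjusted p = 8.8e-11) for PCpY1_MSY and -1.40 (SE 0.13, adjusted p = 1.5e-11) for CpXY17_X. Replicate 1 at S3 held CpXY41_MSY at 72606 CPM and replicate 1 at S4 held it at 17351 CPM, each at the level of the other period. The split was 19 up and 20 down with at least 10 counts in 3 libraries. With table totals in place of scaled ones 52 features passed, 15 up and 37 down, and the median of all features moved from -0.07 to -0.20.

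In stamens the change with age was the broadest of the 3 organs by count of features. CpXY13_X had no counts in S1 to S3 stamens and stood at 23771 ± 8375 CPM at S4 and 43070 ± 2278 CPM at S5 (n = 3 each), a rise of at least 7906-fold over the groups, and CpXY13_MSY reached 30646 ± 1927 CPM at S5. CpXY10_MSY, of a pair with too few female counts to class, was near 0 until S3, at 4245 ± 883 CPM at S4 and at 12590 ± 12937 CPM at S5. CpXY15_X fell from 8542 ± 1242 CPM at S1 to 572 ± 446 CPM at S5 and CpXY17_X from 9700 ± 2141 to 374 ± 79 CPM, both of partly shared pairs, and PCpY1_MSY fell from 2461 ± 489 to 28 ± 27 CPM. CpXY21_X did not follow age, at 10824 ± 1498 CPM at S3, 1468 ± 347 CPM at S4 and 10244 ± 6913 CPM at S5.

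The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment passed 91 of 139 features in stamens, 37 up and 54 down. Of 67 X-located features 20 rose, 27 fell and 20 did not pass (47 when adjusted over the list alone), and of 72 Y-located features 17 rose, 27 fell and 28 did not pass (44 when adjusted over the list alone). Log2 changes were 3.49 (SE 0.21, adjusted p = 1.3e-18) for CpY17_MSY, 2.81 (SE 0.36, adjusted p = 5.4e-09) for CpY1_MSY, -3.13 (SE 0.24, adjusted p = 2.9e-15) for CpXY15_X, -3.11 (SE 0.14, adjusted p = 4.3e-23) for CpXY17_X and -4.71 (SE 0.46, adjusted p = 6.4e-12) for PCpY1_MSY. CpXY4_X, of a pair with too few female counts to class, had 0 counts in S1 to S3 stamens and was at least 1541-fold higher later. Its adjusted p was 6.2e-06 by edgeR and 0.14 by DESeq2, where its log2 change was 8.87. Scaling moved the split, to 52 up and 47 down on X features (median of all features from -0.11 to 0.05) and to 23 up and 75 down with table totals (median -0.55). Its direction also turned with the features tested, to 57 up and 39 down with at least 10 counts in 3 libraries and 54 up and 43 down without a filter, and in a fit of the stamen groups alone (54 up and 44 down).

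The change with age differed between stamens and pistillodes for 66 of 139 features by an edgeR quasi-likelihood test of the difference itself with Benjamini-Hochberg adjustment, 21 with a higher and 45 with a lower change in stamens. Among X-located features 11 were higher, 24 lower and 32 did not pass (36 when adjusted over the list alone), and among Y-located features 10 were higher, 21 lower and 41 did not pass (30 when adjusted over the list alone). CpXY36_X of a shared pair (2.30, SE 0.13, adjusted p = 2.6e-18) and CpXY14_X (2.41, SE 0.17, adjusted p = 9.1e-16) gained more in stamens on the log2 scale. CpXY24_MSY of a shared pair (-2.42, SE 0.15, adjusted p = 1.9e-17) and CpXY15_MSY of a partly shared pair (-3.39, SE 0.27, adjusted p = 3.2e-14) lost more. Between pistillodes and pistils 29 features differed in their change, 15 higher and 14 lower in pistillodes, with CpXY19_MSY at 1.87 (SE 0.34, adjusted p = 8.2e-05), CpXY42_MSY at 1.48 (SE 0.23, adjusted p = 5.3e-06) and CpXY34_X at -0.99 (SE 0.13, adjusted p = 2.6e-07), all of shared pairs, and CpXY17_X of a partly shared pair at -0.86 (SE 0.17, adjusted p = 0.00021). In that contrast 7 X-located features were higher, 7 lower and 53 did not pass (14 when adjusted over the list alone), and 8 Y-located features were higher, 7 lower and 57 did not pass (15 when adjusted over the list alone). The even split of that contrast turned under several settings, among them DESeq2 (15 higher and 16 lower). With table totals the splits were 11 and 59, and 11 and 31, with medians of all features at -0.34 and -0.23 in place of -0.04 and -0.05, and on X features the first of these medians was 0.08.

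Within male libraries the Y copy of a separate pair can be set against its X copy without scaling between libraries, a comparison added after the data were seen. Pairs were classed as separate from female counts alone. These cannot show Y reads that were counted at the X copy or lost, so a low Y share need not mean low Y expression. Across male buds, pistillodes and stamens, 13 of 15 pairs departed from equal counts at both copies by limma with Benjamini-Hochberg adjustment, 4 with more at the Y copy and 9 with more at the X copy. The 15 leave out PYCpXY7, whose Y copy had no counts in many male libraries. Over all male libraries that copy took 3.83% of the pair's counts. Equal counts are not equal levels where annotated exons differ in length. Per exon base 14 of 15 pairs departed, 5 with the Y copy and 9 with the X copy higher, and CpXY5, with 1101 exon bases on the X and 596 on the Y, moved from 0.06 (adjusted p = 0.082) to 0.95 (adjusted p = 7.0e-19). The Y copy of CpXY7 had more counts (log2 ratio 1.02, SE 0.08, adjusted p = 2.6e-11), and those of PYCpXY5 (-3.84, SE 0.07, adjusted p = 8.5e-24), PXYCpXY1 (-3.17, SE 0.08, adjusted p = 2.9e-21) and CpXY9 (-0.57, SE 0.02, adjusted p = 4.8e-19) had fewer. The median over the 15 pairs was -0.13 (interquartile range -0.40 to 0.18). Stamens and pistillodes differed in 10 of 16 pairs, 4 with a higher and 6 with a lower Y share in stamens. The Y share of CpXY3 was 47.7% in stamens and 37.2% in pistillodes (log2 ratio 0.62, SE 0.06, adjusted p = 9.3e-08), and that of CpXY7 was 61.1 and 71.8% (-0.81, SE 0.18, adjusted p = 0.0011).

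Pollen and S5 stamens differed in 8 of 13 pairs by limma with Benjamini-Hochberg adjustment, in 4 pairs without stamen replicate 1 or stamen replicate 2, and in 5 without pollen replicate 3. The Y share of CpXY14 was 82.3 ± 1.97% in pollen and 28.8 ± 4.74% in S5 stamens (n = 3 each; log2 ratio 3.53, SE 0.25, adjusted p = 4.1e-17). For CpXY8 the shares were 16.6 ± 6.46 and 46.7 ± 1.01% (-2.15, SE 0.29, adjusted p = 2.7e-06), and for CpXY5 18.5 ± 4.24 and 44.1 ± 4.79% (-1.81, SE 0.25, adjusted p = 4.1e-08). Late and early stamens differed in 11 of 16 pairs. CpXY14 went from 63.3 ± 3.03% at S3 to 26.4 ± 2.40% at S4 (late against early -1.70, SE 0.14, adjusted p = 3.5e-07). CpXY6 went from 34.6 ± 1.25% at S3 to 64.0 ± 3.49% at S4 (late against early 0.78, SE 0.09, adjusted p = 4.1e-06). Its share was 45.8 ± 3.11% at S1, 43.9 ± 3.72% at S2 and 45.2 ± 1.36% at S5, so its late rise lay at S4. PYCpXY7 held 23.3 ± 10.7% at S4 and 0% at S3 and S5 (4.00, SE 0.31, adjusted p = 3.4e-07). In pistillodes 5 of 15 pairs differed with age, among them CpXY5 (-0.45, SE 0.11, adjusted p = 0.012). Only 3 did without replicate 1 or 2 at S1, replicate 1 or 2 at S2, replicate 2 at S3, at S4 or at S5, and without replicate 1 at S1 and S2 and replicate 2 at S3 together 0 did (limma, with 4 at an unadjusted p under 0.05).

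**Figure D4:**
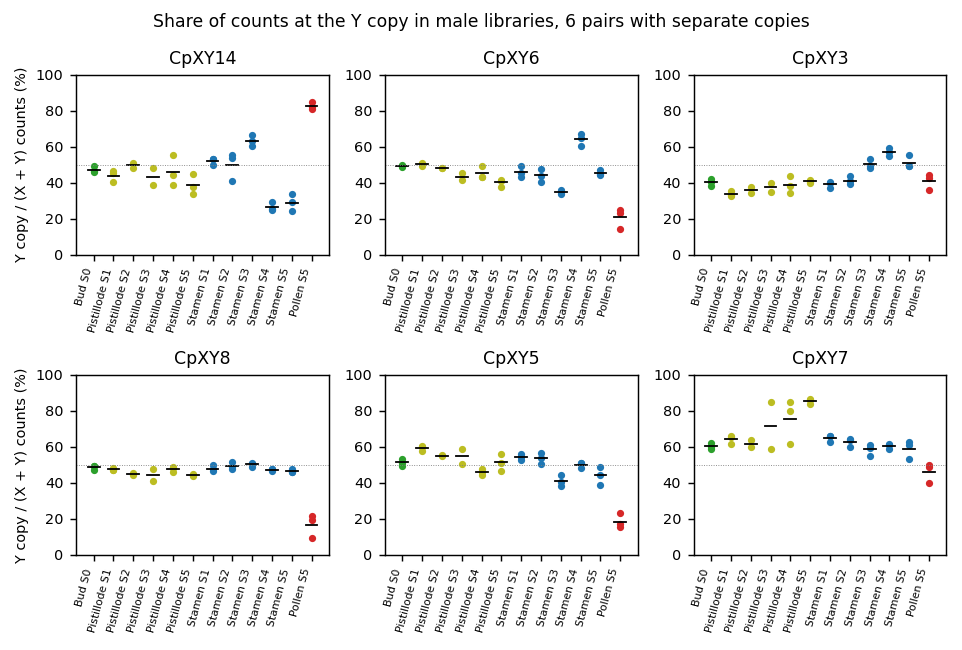
Share of the pair's counts at the Y copy (vertical axes, percent) in male groups for 6 pairs with separate copies; points are libraries and short bars are group means, with a dotted line at 50%. CpXY14 is at 26.4% in S4 stamens and 82.3% in pollen, while CpXY8 and CpXY5 are at 16.6 and 18.5% in pollen.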

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

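The tests on the pistillode libraries, on PCpY4_MSY and on the total of stamen replicate 3 were chosen only after the result was seen. The test of pollen features in stamen replicate 3 and the splits of the samples were chosen earlier.

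The change from early to late stages differed between stamens and pistillodes for 66 features by a test of the difference itself. Of 100 splits 1, the labelled one, gave as many (highest other 59). These splits exchanged organ labels within stages, so they also broke up any difference between the organs at a stage. They cannot exclude chance for the change with age alone. Among the 66 features the difference on the log2 scale was 3.30 for CpY17_MSY and -3.39 for CpXY15_MSY. CpXY18_X stood at 4.52 (adjusted p = 0.011), and at 3.37 (adjusted p = 1.00) without pistillode replicate 1 at S2 and 4.30 (adjusted p = 0.066) without pistillode replicate 1 at S3. PCpY4_MSY stood at -3.15 (adjusted p = 0.0499) and its call was lost or turned in 19 of 28 fits with 1 library left out, with -0.85 (adjusted p = 0.65) without pistillode replicate 3 at S4 and 0.20 without replicate 3 at S5. Without both it passed in the opposite direction, at 2.50 (adjusted p = 0.023).

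Between pistillodes and pistils the change with age differed for 29 features, and 5 of 100 splits gave as many, so chance is not excluded. The highest other split gave 88, several times the count of the labelled split. These splits exchanged organ labels, and with them sex, within stages. A split can thus carry the contrast of the sexes into the change with age. The splits therefore cannot decide whether that change differed. The difference was 1.87 for CpXY19_MSY and 3.95 for PCpY4_MSY, whose call was lost in 13 of 28 fits with 1 library left out, with 1.65 (adjusted p = 0.45) without pistillode replicate 3 at S4 and 0.60 (adjusted p = 0.92) without replicate 3 at S5. PCpY1_MSY stood at -4.17, and at -2.85 (adjusted p = 1.00) without pistil replicate 2 at S4. Its counts in females were few, with 27 over all female libraries and at most 5 in any of them. PYCpXY22_MSY had 18 counts over late pistils and 6 over early ones. For both features the pistil side of the difference thus rests on few counts, and the size of the difference is uncertain. PYCpXY22_MSY stood at -1.89, and the libraries whose removal ended its call were pistil replicate 2 at S4 (-0.92, adjusted p = 0.65), replicate 3 at S1 (-1.71, adjusted p = 0.061), replicate 3 at S2 (-1.70, adjusted p = 0.066) and replicate 1 at S5 (-1.70, adjusted p = 0.067).

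For the other counts, where 100 splits were drawn, a share under 0.05 of them gave as many features as the labelled one. Random divisions of these samples thus seldom gave such counts, although the share rests on 100 splits only. For pistillode against pistil and stamen against pistil the splits mixed female with male libraries. Females carry no Y, so a high rank of the labelled split was set in advance there. Those 2 shares say nothing beyond the difference of sex. As many features came from 1 split, the labelled one, for pistillode against pistil (115, highest other 96), stamen against pistillode (71, highest other 63), stamen against pistil (116, highest other 101), late against early pistil (23, highest other 5) and late against early stamen (91, highest other 67). For late against early pistillode 2 of 100 splits gave as many as the labelled 33, and the highest other gave 36. Splits were too few, at 10, for a share under 0.05 for buds (90, highest other 0), ovule against pistil (12, highest other 2) and pollen against stamen (100, highest other 6).

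Pistillode replicate 1 at S3 held CpXY41_MSY at 72606 CPM and CpXY7_MSY at 51055 CPM, levels of late pistillodes, while replicate 1 at S4 held 17351 and 15346 CPM, levels of early ones. An exchange of the labels of both libraries needs their other features to follow. Over 126 other features, replicate 1 at S4 correlated better with late pistillodes (margin 0.35) and replicate 1 at S3 better with early ones (margin -0.30). The smaller of both margins for an exchange was thus -0.35, which argues against it. Both margins were the weakest of their periods, next to 0.36 for replicate 3 at S4 and -0.49 for replicate 2 at S3. Each was also taken with the other library under its given label. A difference in age between flowers of 1 size class stays open and was not tested.

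PCpY4_MSY took 28.2% of the counts of pistillode replicate 3 at S5 and 11.1% of replicate 3 at S4, against 0.0563 to 2.83% in the other 11 pistillode libraries. Females held at least 12 counts in every library, consistent with reads from a sequence outside the Y. Over the 13 pistillodes its CPM fell with the total count (Spearman -0.63, permutation p = 0.0239, and Pearson on log2 CPM -0.74, permutation p = 0.00352). Spearman was -0.40 without the 2 farthest libraries. CPM is divided by the scaled total, so part of this fall is built in. The permutations do not allow for that, so these p-values cannot decide whether libraries with low totals hold more PCpY4_MSY. The CPM rose with the number of other features detected at 1 depth (Spearman 0.76, permutation p = 0.0031, adjusted over both relations 0.0062; Pearson 0.77, permutation p = 0.00216, and 0.80 without the 2 farthest). Background reads may thus contribute. Before scaling, replicates 3 at S5 and S4 also held the most PCpY4_MSY counts, 10615 and 2384, with 1832 the next highest. A low total alone does not give such counts. No biological explanation was tested.

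Stamen replicate 3 at S5 held CpY17_MSY at 29950 CPM, against 133100 and 184200 CPM in replicates 1 and 2. Its total was 1.11 times the lower of theirs, which argues against fewer counts. The 39 features higher in pollen than in S4 stamens had a median log2 ratio of -0.47 to the other replicates and the 67 lower in pollen one of 0.37, a difference of -0.84 (permutation p = 1e-05, the smallest these permutations can give; across features, which are not independent). Less pollen RNA in that library is a candidate explanation. A difference in flower age stays open and was not tested.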

How the results depend on the processing

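The tests on features without shared copies, without libraries that stood apart, and all tests of the Y to X ratio were chosen only after the result was seen. Counts of changed features stayed within 1.5 times their value under the other scalings, filters, fits and tests, except where given here.

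With shared and partly shared pairs both left out, 65 features remained, fewer by construction. Among these 65 the counts were 49 for buds, 53 for pistillode against pistil, 24 for stamen against pistillode, 54 for stamen against pistil, 4 for ovule and 36 for pollen. They were 0 for late against early pistil (edgeR, 13 at an unadjusted p under 0.05), 8 for pistillode, 36 for stamen, and 20 and 4 for the differences between organs. Late against early pistillode gave 52 with table totals, and its ratio test 2 with the replicate block and 0 without 3 libraries (limma, 4 at an unadjusted p under 0.05); the cause was not tested. PCpY4_MSY reversed in the difference of stamen and pistillode, to 0.20 without pistillode replicate 3 at S5 and 2.50 without that library and replicate 3 at S4, where it passed in the opposite direction (adjusted p = 0.023), and in that of pistillode and pistil to -1.70 without both, and with each library left out the former ran from -4.17 to 0.20; beyond the removal of these libraries the cause was not tested.

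With each library left out, counts ran from 82 to 88 for buds, 114 to 118 for pistillode against pistil, 64 to 74 for stamen against pistillode, 114 to 117 for stamen against pistil, 5 to 11 for ovule, 91 to 103 for pollen, 18 to 34, 29 to 37 and 85 to 97 for late against early pistil, pistillode and stamen, and 58 to 68 and 24 to 36 for the differences. Ratio counts ran from 8 to 10 for stamen against pistillode, 4 to 7 for pollen, 8 to 13 for late stamen, 3 to 5 for late pistillode and 13 to 14 for the mean of males, which gave 14 per exon base. Ovule gave 5 without pistil replicate 2 at S5 or ovule replicate 3. Where a library left 1 in a group, that library was assumed to vary like the others.

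Of 2353 values of named features under other settings, 2269 kept direction and call, 82 lost the call and 2 reversed; of 3940 with 1 library left out, 3801, 138 and 1. Of 1288 ratio values, 1176 kept both and 112 lost the call. Counting other filters, late against early stamen gave 57 up and 39 down with at least 10 counts in 3 libraries and 54 up and 43 down without a filter. Same-number libraries showed no common pairing: the median correlation of residuals was 0.00597 over 41 same-number pairs and -0.00353 over 82 others. Of the 41, 13 exceeded 0.1 and the lowest was -0.355. These pairs included female with male libraries, which cannot share flowers. Their median therefore cannot exclude that stamens and pistillodes of 1 number were paired. The alternatives planned for CpMDAR4 were not run. Depth limits what can be seen at features near 3 counts per group, above all in pollen, with totals of 27741 to 28555 counts.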

Other observations

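The tests of copy spans and of X dose were chosen only after the result was seen, as was the ratio of Y to X counts.

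Across 57 pairs, the share of female counts at the Y copy rose along the X map (Spearman 0.81, permutation p = 1e-05, the smallest these permutations can give; across genes, which are not independent replicates). From CpXY33 on, 13 of 18 pairs lay above 50%, with a median of 56.3% (27.0 to 86.0%), and CpXY50 and CpXY49 stood at 83.0 and 72.3%. A hypothesis is that copies at the far end of the map are near-identical, so that reads map to both. The difference in span between X and Y copies had a median of 0.265% over 25 shared pairs and 11.6% over 21 separate pairs, a difference of -11.3% (permutation p = 0.0324), consistent with it, although sequences were not compared. With such reads counted at each place, identical copies would give about 50%, so the shares well above it do not follow from the hypothesis, and their cause was not tested.

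A further hypothesis is that X copies of separate pairs were lower in males because males have a single X. Set against shared pairs as the reference, 16 such X copies were lower in male buds by a median log2 difference of -0.96 (95% bootstrap interval over pairs -1.28 to -0.63) and in pistillodes by -0.95 (-1.24 to -0.62). The sum of X and Y counts of the same pairs differed from the shared pairs by -0.08 (-0.51 to 0.35) and -0.03 (-0.43 to 0.37). These values are in line with a dose of 1 X if features of shared pairs count reads of both chromosomes, which was not tested. Genes are not independent replicates, and the interval rests on 10000 resamples over pairs.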
